A study of Mus musculus with 10 samples.

How the data were processed

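Single cells were measured in 10 libraries from the ventricular-subventricular zone (V-SVZ), the germinal tissue along the lateral ventricles of the adult mouse forebrain. Per the labels' protocols, the dorsal and lateral V-SVZ were dissected together and dissociated with papain, and cells that took up DRAQ5 and excluded propidium iodide were sorted as viable. Libraries were made with the 10x Genomics Chromium Single Cell 3' kit, which reads the 3' end of polyadenylated RNA and tags each molecule with a unique molecular identifier (UMI). The deposited matrices hold, per the file headers, UMI counts per gene and cell barcode written by Cell Ranger 3.1.0. The submitters' processing notes name Cell Ranger 3 and the mouse build mm10. No header or label says how cell barcodes were chosen or which annotation was used. The CD1 matrices list 31053 genes and those of the other strain 27999, among them the EYFP reporter transcript. The 27514 genes listed in both were used, and 0.130% to 0.267% of the UMIs of a library fell outside them. Gene positions were taken from GENCODE vM21 on GRCm38 (mm10).

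All values given here were computed from those counts. Barcodes with at least 500 UMIs, at least 300 genes and at most 15% mitochondrial UMIs were kept, which removed 0.450% to 9.09% of the barcodes of a library. Doublet scores came from Scrublet in scanpy 1.11.5. The highest-scoring cells were removed, 54 to 1069 per library, in some beyond the expected 0.8% per 1000 cells (2.05% to 8.85%). The automatic Scrublet threshold (0.0643% to 4.56% of cells) was not used, as it called nearly none in some libraries. Of 52469 barcodes, 47794 cells were used, 2510 to 9997 per library. The median cell held 4999 to 12332 UMIs and 1895 to 2941 genes, depending on the library.

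Counts were scaled to 10000 per cell and logged, and the 2000 most variable genes within libraries were scaled (limit 10 SD) and reduced to 40 principal components. A graph of 15 neighbours and Leiden clustering at resolution 2 with seed 0 gave 55 clusters, with no correction between libraries. A cluster of at least 30 cells took the class, from 20 marker lists, with the highest mean marker level relative to other clusters. At least 3 of that class's markers had to be seen in at least 10% of the cells each, and its 10 leading genes had to hold at least 1 of them and more than of any other class. Each named cluster held 3 or more, except cluster 24 of microglia (893 cells), led by Ccl4, Ccl3 and Il1b, which held 1. This rule was set after the clusters had been seen, as was a further one that left cluster 48 unnamed for its lead of Eomes and Neurog2. This gave 14 named classes and 8 unnamed clusters. The class called astroglia holds astrocytes and quiescent neural stem cells together, and the class of transit-amplifying cells was named by cycling genes. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, igraph 0.11.9, scikit-learn 1.9.0 and matplotlib 3.10.9 were used.

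UMI counts were summed per library and class, so that the library was the unit of every test. The p-values measure the spread between libraries, and nothing in the labels says that each library is a separate animal. Gene tests used edgeR 4.0.16 in R 4.3.3 with TMM scaling, its filter on low counts and its robust quasi-likelihood test, with Benjamini-Hochberg adjustment over the genes of a class and a threshold of 0.05. At 3 weeks the model held strain and treatment on 7 libraries, 4 CupRap against 3 controls. The 0-week comparison (2 libraries against 1), the comparison of CupRap at 3 weeks with CupRap at 0 weeks (2 against 2) and the difference between the strains used a mean per group on all 10 libraries. A lone control library was assumed there to vary like the other groups. Classes needed 20 cells in every library, which 7 classes met, and oligodendrocyte precursor cells (OPCs) and committed oligodendrocyte precursors were fitted without the library that held fewer. Numbers of cells per class were tested with the same edgeR test with the total of cells as the library size, and at 3 weeks also with an exact 2-sided permutation test of the shares within strains. All adjusted p-values below come from edgeR so adjusted unless another tool is named.

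The marker lists, 27 gene lists with the classes they apply to, the cell filters, the tests and most alternatives were fixed before the data were examined. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists and classes of a comparison, and again with an estimated correlation. Genes were named by a fixed rule. It took up to 6 rises and 6 falls per class and comparison that were largest among genes past the threshold with a mean log2 CPM of at least 5, where every CupRap library lay beyond every control of its strain and time. Unnamed gene models and mitochondrial, ribosomal and hemoglobin genes were left out of it. It further took up to 4 members with the smallest p from each list that applies to the class, and 12 genes always looked up. Values are CPM (counts of the class scaled to a common total), and errors are standard errors (SE) for log2 fold changes and standard deviations (SD) for levels. For a gene with 0 UMIs in 1 group, the fold is a lower bound against 3 counts over that group, and with 1 to 3 UMIs it is the pooled ratio with its 95% interval, which covers counting error only.

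The reporter was to be read against CD1 libraries as background. Their gene list lacks it, so microglia and endothelial cells of the reporter strain served instead. Shares of cells with the reporter carry exact Clopper-Pearson intervals, and were taken again in cells thinned to 3000 UMIs.

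The tests of genes and lists in 3 classes were tried on simulated counts with 200 genes changed by known folds. The test of shares at 3 weeks was tried on a simulated change. Cell filters, clustering, class names, free RNA subtraction and the reporter shares were not simulated. At 3 weeks, 18.8%, 73.4% and 90.8% of the genes changed 1.5-fold, 2-fold and 4-fold were called in microglia (11560 genes). In oligodendrocytes (11020 genes) these shares were 28.1%, 73.8% and 96.8%, and in astroglia (11480 genes) 16.9%, 60.0% and 93.5%. At 0 weeks a 2-fold change was called for 16.1%, 3.23% and 14.3% of genes in these classes and a 4-fold change for 68.9%, 39.1% and 61.5%. Of the 30 to 132 genes called per simulation, 3.79% to 13.6% had not been changed. Real data may differ.

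Fixed alternatives were DESeq2 1.42.0 (its test, and its size factors within edgeR), no filter on low counts, doublets kept, a stricter cell filter (500 genes, 10% mitochondrial), the other clustering at resolution 1, each strain alone, all 10 libraries in the 3-week model, both CD1 controls as 1 group, the replicate number as a block, other denominators for the shares, and each library left out in turn. Alternatives added after seeing the data were a common minimum of 3463 UMIs per cell in every library, sums from which free RNA of microglia and oligodendrocytes was subtracted, a crossed replicate block, and a reporter share in thinned cells. Microglial and oligodendrocyte RNA in the sums of other classes was estimated from fixed lists. Sex and age were not in the labels and were not modelled.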

Results

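RNA was counted in single cells of the V-SVZ after demyelination, to ask how the cells of this stem cell niche respond and which signals microglia offer to cells that make myelin. The mice had been given cuprizone in the chow, a copper chelator that kills oligodendrocytes, with injections of rapamycin, an inhibitor of mTOR, for 6 weeks (CupRap), or normal chow and vehicle. No library came from mice given only 1 of these drugs. Cells were collected after 3 weeks of recovery or at its start (0 weeks), from the outbred strain CD1 or from NesCreERT2;EYFP mice. In the latter, called the reporter strain here, a Nestin-driven inducible Cre switches on EYFP in neural stem cells and their progeny. The labels do not say when it was induced.

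At 3 weeks there were 2 CupRap libraries and 1 control of CD1, and 2 of each of the reporter strain. At 0 weeks there were 2 CupRap libraries and 1 control, all CD1. The labels conflict for the 0-week groups. The treatment field of the library titled CD1 control at 0 weeks gives 3 weeks of recovery. That of those titled CD1 CupRap at 0 weeks gives vehicle. The titles were followed. Total counts were 40996363 and 32167350 UMIs for the CD1 controls at 0 and 3 weeks. They were 73057425 and 44081500 UMIs for CD1 CupRap replicates 1 and 2 at 0 weeks, and 33083246 and 31348327 at 3 weeks. The reporter strain held 48710397 and 37475236 UMIs in its control replicates 1 and 2, and 53360030 and 73820835 in its CupRap replicates. CD1 CupRap replicate 2 at 0 weeks came with 4000 barcodes, the lowest of 3463 UMIs, against 500 to 510 in the other libraries.

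Microglia, the resident immune cells of the brain, made up 38.2% ± 10.8 (SD, n = 4) of the cells of CupRap libraries at 3 weeks and 13.4% ± 4.13 (n = 3) of controls. Their share rose by a log2 fold of 1.64 ± 0.26 (SE; adjusted p = 0.0056). The share of astroglia, the class with the quiescent stem cells, fell by 1.93 ± 0.26 on the log2 scale (adjusted p = 0.0054), from 14.9% ± 2.21 to 3.79% ± 0.714. With the replicate number as a block both calls were lost (1.67 and −1.90, adjusted p = 0.068 each), and with TMM over classes that of microglia (1.498, adjusted p = 0.13). Microglia were 29.2% ± 3.05 of CD1 CupRap cells against 8.92% in the control, and 47.3% ± 3.47 against 15.6% ± 2.08 in the reporter strain. Astroglia were 3.37% ± 0.312 against 13.4% in CD1 and 4.21% ± 0.853 against 15.7% ± 2.54 in the reporter strain. Border macrophages, the immune cells of meninges and choroid plexus, rose by 1.86 ± 0.48 (adjusted p = 0.039), from 0.196% ± 0.165 to 0.519% ± 0.365. That call was lost without any 1 library other than the reporter control replicate 1, with an adjusted p of 0.051 to 0.12, and with the block (0.18) or TMM over classes (0.17). Committed oligodendrocyte precursors were 3.10% ± 1.27 of CupRap cells against 0.641% ± 0.481 (2.15 ± 0.80, adjusted p = 0.13), and 0.035 without the reporter control replicate 2. Neuroblasts, the migrating young neurons, were 24.7% ± 10.9 against 34.4% ± 14.6 of all cells (adjusted p = 0.13) and 45.3% ± 10.8 against 44.9% ± 15.04 of neural-lineage cells (log2 −0.07, adjusted p = 0.98). Oligodendrocytes were 11.2% ± 3.56 against 11.7% ± 7.13 (adjusted p = 0.77). The exact permutation p was 0.0556 for microglia, astroglia, border macrophages, committed precursors, neuroblasts and mural cells, the smallest that 18 permutations within strains can give. Classes share the total of cells, so more cells of 1 class lower the share of the others.

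**Figure D1:**
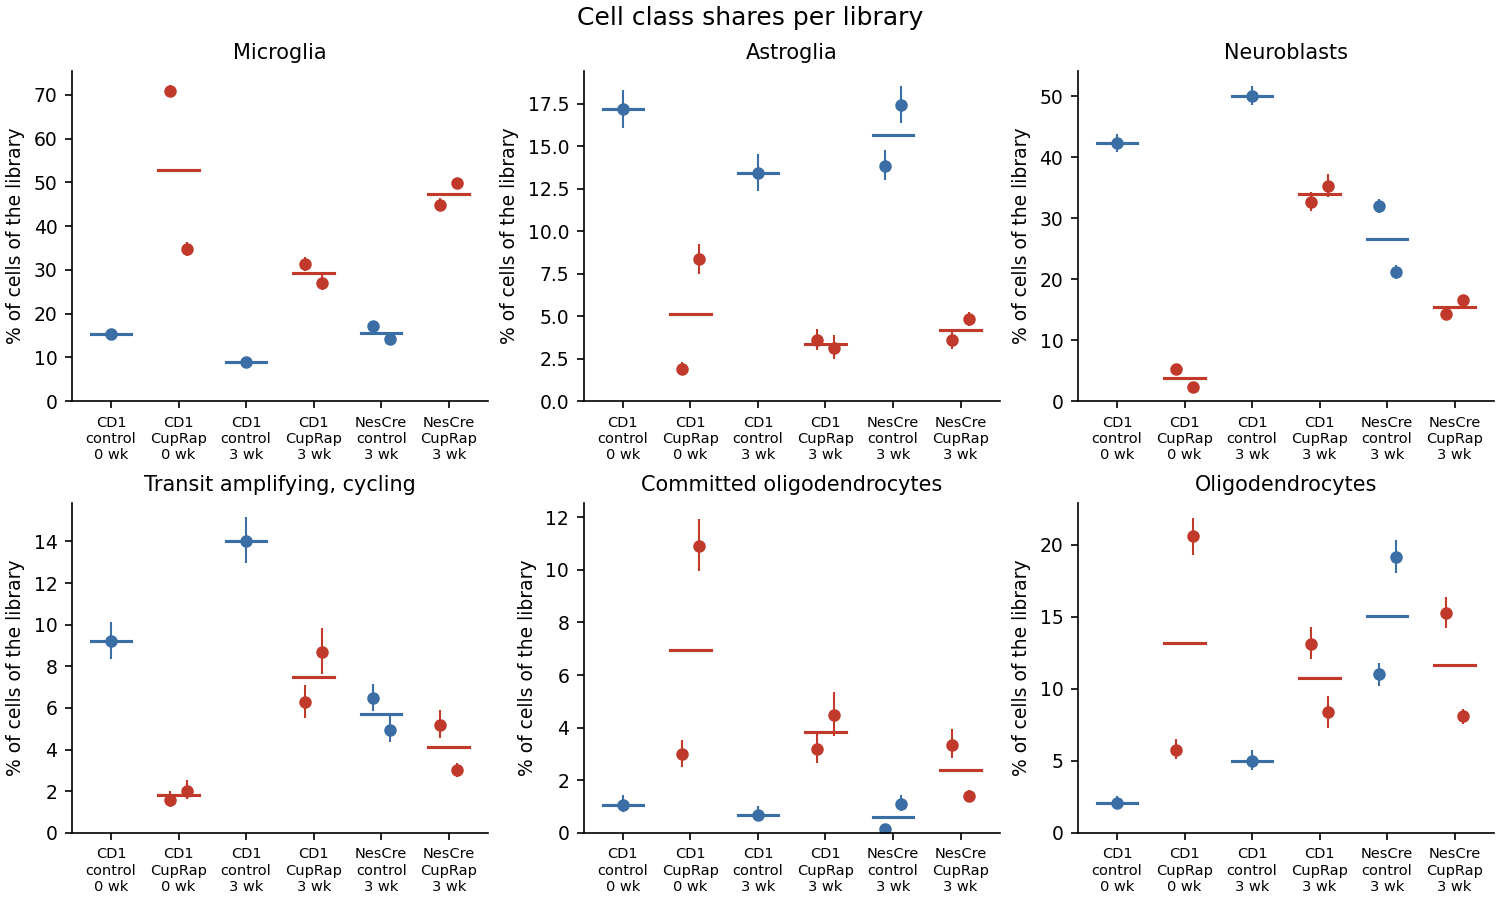
Share of cells (percent) per class and library, with the libraries as points with 95% intervals and the group means as lines, CupRap in red. Microglia were 38.2% of CupRap cells at 3 weeks and 13.4% of control cells, and astroglia 3.79% and 14.9%.

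In microglia at 3 weeks 29 of 29 tested disease-associated genes rose (29 adjusted over the list alone), and of 21 genes of lipid handling 17 rose and 2 fell (17 and 2 adjusted over the list alone). Gpnmb, a glycoprotein of phagocytic cells, had no UMI in control microglia and 379 ± 94.4 CPM (SD, n = 4) after CupRap, at least 1648-fold higher. Igf1, a growth factor for oligodendrocyte precursors, rose from 1.87 ± 1.25 (n = 3) to 269 ± 74.7 CPM, a log2 fold of 7.17 ± 0.29 (SE; adjusted p = 2.6e-08). Apoe, the main lipid carrier of the brain, rose from 1557 ± 865 to 141250 ± 25408 CPM (6.49 ± 0.27, adjusted p = 1.9e-08). The lipid genes Fabp5 (6.27 ± 0.20), Lpl (4.33 ± 0.23) and Plin2 (3.15 ± 0.17), the last on the surface of lipid droplets, rose as well, with Lgals3 (6.31 ± 0.27) and the lysosomal Cd63 (3.25 ± 0.22). Apoc4 rose by 9.47 ± 0.35, Apoc1 by 7.90 ± 0.40 and the scavenger receptor Colec12 by 7.53 ± 0.38. Atp6v0d2, of the lysosomal proton pump, had no UMI in controls and was at least 218-fold higher. Ms4a7 had 3 control UMIs and a pooled ratio of 492 (95% interval 168 to 2388). P2ry12, a receptor of resting microglia, fell by 2.45 ± 0.18 (adjusted p = 9.2e-07), from 2753 ± 385 to 516 ± 114 CPM. Tmem119 fell by 2.22 ± 0.15, Selplg by 2.00 ± 0.14 and the fructose transporter Slc2a5 by 2.65 ± 0.14. Camk2n1 fell by 2.51 ± 0.22, Lrba by 2.55 ± 0.25, Ecscr by 2.81 ± 0.34 and Serpinf1 by 2.41 ± 0.31. Spp1, a secreted matrix protein, rose from 31.1 ± 44.3 to 3918 ± 1045 CPM (7.08 ± 1.42, adjusted p = 0.023). The cytokine Osm was at 67.0 ± 28.6 against 33.8 ± 35.5 CPM (adjusted p = 0.30). The Spp1 call was lost without the CD1 control (adjusted p = 0.067), CD1 CupRap replicate 2 (0.062) or reporter CupRap replicate 1 or 2 (0.064 and 0.050).

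Of 24 genes of resting microglia 22 fell (22 adjusted over the list alone). Of 28 lysosomal genes 21 rose and 1 fell (23 and 1 adjusted over the list alone). Of 25 interferon response genes 21 rose (21 adjusted over the list alone), such as Oas1a by 5.10 ± 0.47. Of 17 antigen presentation genes 16 rose (16 adjusted over the list alone), such as Cd74 by 4.76 ± 0.22. Of 34 secreted ligands 16 rose and 4 fell (16 and 4 adjusted over the list alone), 1 of the latter, Bmp2k, being a kinase that the list holds in error. Of 13 mitochondrially encoded genes 12 rose (12 adjusted over the list alone), and of 27 cell cycle genes 1 changed, a fall that was lost when adjusted over the list alone. Of 22 cholesterol synthesis genes 3 rose (2 adjusted over the list alone), of 19 stress response genes 9 rose and 1 fell (10 and 2 adjusted over the list alone), and of 21 dissociation genes 4 fell (4 adjusted over the list alone). With an estimated correlation, the list tests of disease-associated and lipid handling genes held (adjusted p = 0.044 each). The others were lost, with an adjusted p with an estimated correlation of 0.12 for antigen presentation, 0.14 for lysosomal, 0.16 for resting microglia, and 0.20 for interferon, ligand and mitochondrial genes. It was 0.46 for stress response and 0.72 for dissociation genes. The list of resting microglia shares 13 of its 24 genes with the markers that named the class. edgeR called 4040 of 12112 genes in microglia, 2269 higher and 1771 lower, and 1634 by more than 2-fold. Among 98 ribosomal protein genes 80 rose. Control microglia of CD1 lay mostly in clusters 8 and 21 and those of the reporter strain in cluster 37, while CupRap microglia lay in clusters 24, 35, 42 and 43 (CD1) and 31, 33, 36 and 50 (reporter strain).

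**Figure D2:**
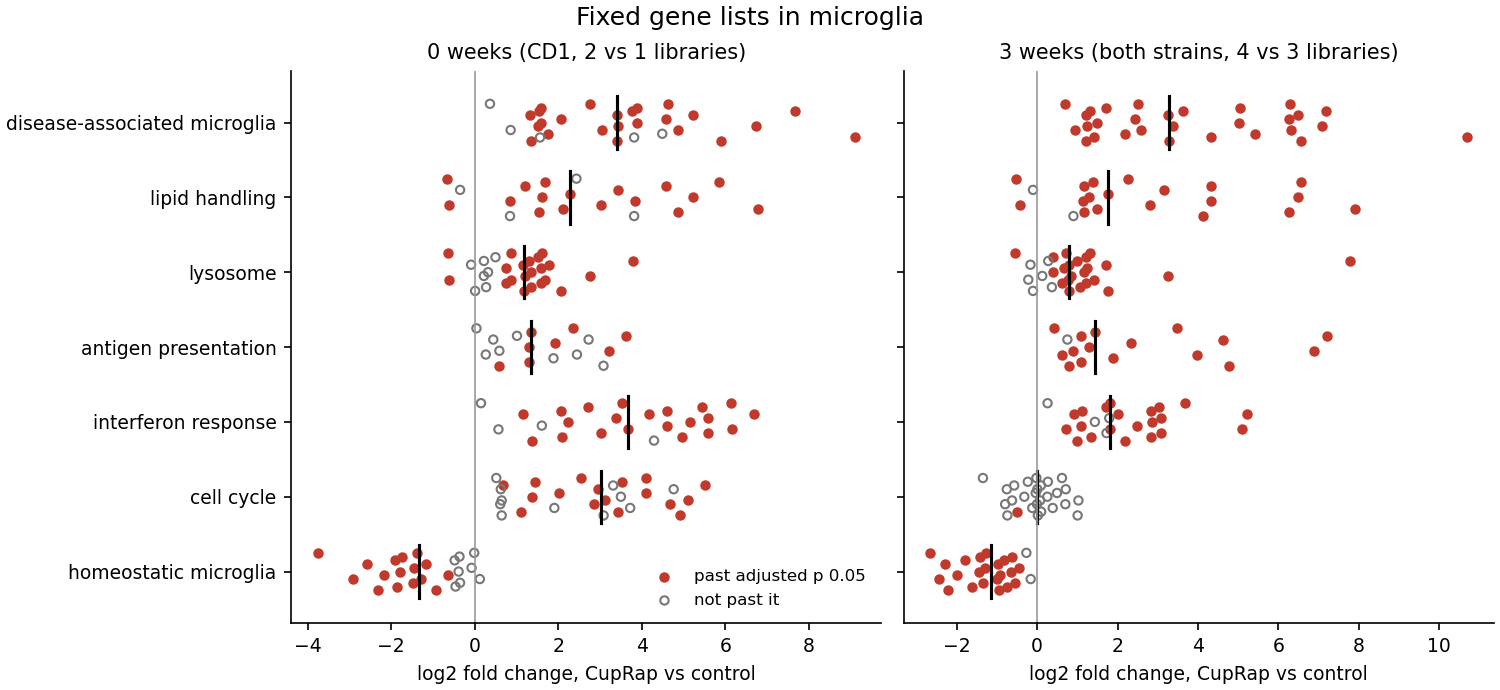
Log2 fold change of each tested gene (points, filled where called) of fixed lists in microglia at 0 and 3 weeks, with list medians as lines. At 3 weeks the 29 genes of disease-associated microglia lie above 0 with a median of 3.28, and 22 of the 24 genes of resting microglia fell.

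Oligodendrocytes, the myelin-forming cells, had higher RNA of several myelin genes at 3 weeks. Tspan2, a membrane protein of myelin, rose from 1449 ± 100 (SD, n = 3) to 3244 ± 309 CPM (n = 4), a log2 fold of 1.16 ± 0.13 (SE; adjusted p = 2.9e-05). The myelin genes Cldn11 (0.98 ± 0.13) and Mog (0.86 ± 0.14, adjusted p = 5.1e-04) rose too. Mbp was at 6995 ± 1118 against 5354 ± 261 CPM (0.35 ± 0.13, adjusted p = 0.088). Carbonic anhydrase Car2 fell by 0.70 ± 0.13 (adjusted p = 0.0018). The adhesion gene Cntn1 rose by 3.24 ± 0.45 and the scaffold gene Slc9a3r2 by 2.93 ± 0.31 (adjusted p = 9.2e-04). The complement gene C4b rose by 4.04 ± 0.62 (adjusted p = 0.016), and the MHC class I gene H2-K1, whose reads near-identical copies may share, by 1.46 ± 0.17. Gstm1 fell by 2.72 ± 0.16 (adjusted p = 8.8e-07), Ndrg2 by 3.05 ± 0.20, Hopx by 3.56 ± 0.42, Htra1 by 2.15 ± 0.29, Pdlim1 by 1.95 ± 0.30 and Selenop by 1.87 ± 0.30. Htra1 is also a leading gene of astroglia, whose free RNA was not estimated, so these falls were not shown to come from oligodendrocytes. The serine synthesis gene Phgdh fell by 0.74 ± 0.11 and the folate enzyme Mthfd2 by 1.17 ± 0.13.

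By fixed lists, 12 of 24 myelin genes rose in oligodendrocytes and 4 fell (13 and 6 adjusted over the list alone; adjusted p = 0.40 with an estimated correlation). Of 20 genes of disease-associated oligodendrocytes 9 rose and 3 fell (11 and 4 adjusted over the list alone; adjusted p = 0.31 with an estimated correlation). Of 13 antigen presentation genes 10 rose (10 adjusted over the list alone; adjusted p = 0.072 with an estimated correlation). Of 14 interferon genes 6 rose and 2 fell (8 and 2 adjusted over the list alone; adjusted p = 0.19 with an estimated correlation). The estimate of microglial RNA was 0.993% ± 0.704 of oligodendrocyte sums after CupRap and 0.310% ± 0.240 in controls (SD). With free RNA subtracted the tests of antigen presentation and interferon genes at the preset correlation had an adjusted p of 6.6e-05 and 0.0032. An estimated correlation was not run on these sums. Of 17 ligand receptors 5 rose and 4 fell (6 and 4 adjusted over the list alone), of 15 stress response genes 4 rose and 3 fell (6 and 3 adjusted over the list alone), of 23 cholesterol genes 1 rose and 2 fell (1 and 2 adjusted over the list alone), and of 20 cell cycle genes 2 fell (1 adjusted over the list alone). The myelin list shares 19 of its 24 genes with the markers of the class. edgeR called 1957 of 11278 genes, 1000 higher and 957 lower, 1890 with free RNA subtracted, and 1300 without the CD1 control and 1294 without the reporter control replicate 1. The C4b call was lost without the CD1 control (adjusted p = 0.0795) or the reporter control replicate 2 (0.0565). Mbp was called without CD1 CupRap replicate 1 (0.040). Cells of both groups lay mostly in cluster 19, those of CupRap further in cluster 20 and those of controls in cluster 6.

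Astroglia at 3 weeks combined a rise of RNA of reactive genes with a fall of RNA of cholesterol synthesis genes. Msmo1, a sterol oxidase, fell by 1.90 ± 0.22 (SE; adjusted p = 6.1e-04), from 424 ± 127 (SD, n = 3) to 112 ± 21.8 CPM (n = 4). Fdft1, which makes squalene, fell by 1.67 ± 0.15 (adjusted p = 1.7e-05), Idi1 by 1.59 ± 0.18 and the sterol sensor Insig1 by 1.68 ± 0.15. Of 23 genes of the cholesterol list 17 fell (1 higher and 22 lower adjusted over the list alone), and the list test held with an estimated correlation (adjusted p = 0.044). Gfap, the intermediate filament of reactive astrocytes, rose from 51.6 ± 26.2 to 639 ± 641 CPM (3.51 ± 0.45, adjusted p = 0.0092). A2m rose by 4.79 ± 0.48, C4b by 1.68 ± 0.18 (adjusted p = 1.3e-04), Cp by 5.29 ± 0.46, the oncostatin M receptor Osmr by 3.76 ± 0.51 and the interferon gene Bst2 by 2.72 ± 0.38. Of 26 reactive genes 16 rose (20 adjusted over the list alone; adjusted p = 0.14 with an estimated correlation). Interferon genes rose in 8 of 17 cases (13 adjusted over the list alone; adjusted p = 0.19 with an estimated correlation) and antigen presentation genes in 4 of 10 (6 adjusted over the list alone; adjusted p = 0.20 with an estimated correlation). Microglial RNA was estimated at 1.12% ± 0.859 of astroglial sums after CupRap and 0.230% ± 0.146 in controls (SD). With free RNA subtracted the tests of these 3 lists at the preset correlation had an adjusted p of 3.2e-44, 2.9e-12 and 1.1e-04. Genes of dormant stem cells fell in 7 of 18 cases (11 adjusted over the list alone; adjusted p = 0.32 with an estimated correlation), such as Hes1 by 1.07 ± 0.17 and Glul by 0.95 ± 0.15. Of 27 cell cycle genes 4 rose (15 adjusted over the list alone; adjusted p = 0.24 with an estimated correlation), such as Mki67 by 1.16 ± 0.22 and Top2a by 1.01 ± 0.20. Of 16 neurogenic genes 2 rose (4 adjusted over the list alone; adjusted p = 0.38 with an estimated correlation). The adhesion genes Ntm and Flrt1 and the glutamate receptor Grm3 fell by 1.77 ± 0.19, 1.76 ± 0.20 and 1.69 ± 0.22. Egfr, the growth factor receptor of activated stem cells, was at 371 ± 64.5 against 320 ± 76.4 CPM (adjusted p = 0.63).

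In astroglia edgeR called 718 of 11730 genes, 337 higher and 381 lower, and 649 with free RNA subtracted. It called 412 without the reporter control replicate 1, 352 without its replicate 2 and 360 without reporter CupRap replicate 1. The Gfap call was lost without reporter control replicate 2 (adjusted p = 0.065) or reporter CupRap replicate 2 (0.058). Control astroglia lay mostly in clusters 15, 18 and 29, CD1 CupRap astroglia most in cluster 29 and reporter CupRap astroglia most in cluster 22.

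**Figure D3:**
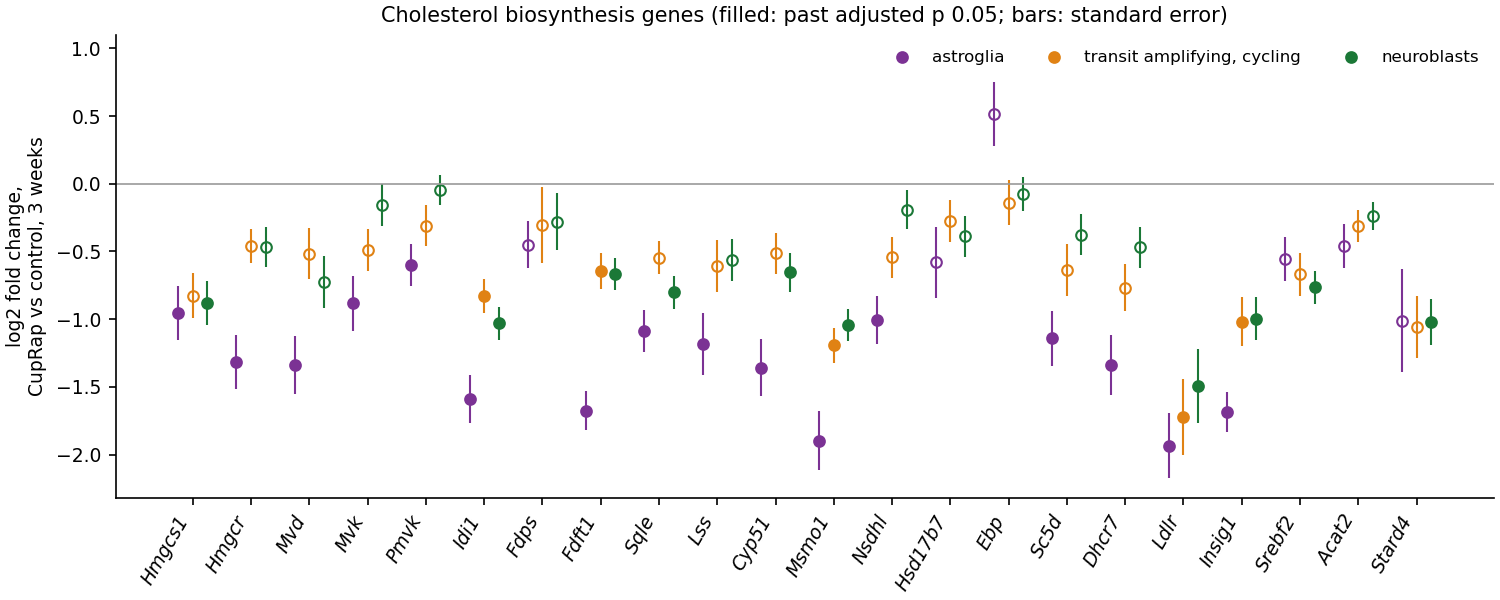
Log2 fold change at 3 weeks (with SE, filled where called) of 22 of the 23 cholesterol synthesis genes in 3 classes, CupRap against control. Over the whole list 17 of 23 fell in astroglia, 10 of 23 in neuroblasts and 6 of 23 in transit-amplifying cells.

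Neuroblasts and the dividing transit-amplifying cells shared a fall of RNA of cholesterol synthesis genes at 3 weeks. In neuroblasts Msmo1 fell by 1.04 ± 0.12 (SE; adjusted p = 2.5e-04), from 65.7 ± 26.0 (SD, n = 3) to 34.1 ± 9.32 CPM (n = 4), Idi1 by 1.03 ± 0.12 and the squalene epoxidase Sqle by 0.80 ± 0.12. In transit-amplifying cells Msmo1 fell by 1.19 ± 0.13 (adjusted p = 3.3e-05) and Idi1 by 0.83 ± 0.13. Of 23 cholesterol genes 10 fell in neuroblasts and 6 in transit-amplifying cells (18 and 19 adjusted over the list alone). The list tests had adjusted p = 0.046 and 0.044 with an estimated correlation. The cholesterol exporter Abca1 rose by 1.16 ± 0.12 in transit-amplifying cells (adjusted p = 2.4e-05), and Mfge8 fell by 1.00 ± 0.13 in neuroblasts. With free RNA subtracted these genes stayed called, Msmo1 with adjusted p = 0.0055 and 8.8e-05 in the 2 classes. In neuroblasts Lyz2, a macrophage gene, rose from 0.683 ± 0.346 to 58.8 ± 31.3 CPM, C1qa by 3.39 ± 0.31 and Apoe by 4.08 ± 0.28. Neuroblast sums held an estimated 1.37% ± 0.780 microglial RNA after CupRap and 0.163% ± 0.122 in controls. With it subtracted Apoe was at 2.23 (adjusted p = 0.73), and 18 genes were called in neuroblasts in place of 157 (138 higher and 19 lower) and 11 in transit-amplifying cells in place of 36. Antigen presentation genes rose in 6 of 14 cases in neuroblasts (12 adjusted over the list alone) and 2 of 9 in transit-amplifying cells (6 adjusted over the list alone; adjusted p = 0.16 with an estimated correlation), and interferon genes in 2 of 12 in neuroblasts (8 adjusted over the list alone). Their list tests in neuroblasts held with an estimated correlation (adjusted p = 0.044 each). With free RNA subtracted the tests at the preset correlation had an adjusted p of 6.6e-14 and 8.2e-04 in neuroblasts and 9.6e-04 for antigen presentation in transit-amplifying cells, and an estimated correlation was not run on these sums. Ligand receptors rose in 3 of 19 cases in neuroblasts (4 higher and 2 lower adjusted over the list alone). The neuroblast count was 92 without the CD1 control and 96 without reporter CupRap replicate 2.

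OPCs and committed precursors were compared in 4 CupRap and 2 control libraries at 3 weeks. In OPCs the metallothionein Mt1 fell by 1.36 ± 0.21 (SE; adjusted p = 6.4e-05), from 344 ± 54.5 to 127 ± 39.3 CPM (SD). The neuronal genes Stmn2 and Tubb3 fell by 4.42 ± 0.42 and 1.79 ± 0.29, with an adjusted p of up to 0.93 (Stmn2, doublet calls kept) and 0.91 (Tubb3, 0-week control added) over the alternatives. C4b rose by 3.48 ± 0.51 (adjusted p = 0.0021), and was at 1.43 (0.56) without the reporter control replicate 2. Pdgfra, the receptor that marks OPCs, was at 1863 ± 205 against 1455 ± 614 CPM (adjusted p = 0.68) and Olig2 at 858 ± 133 against 743 ± 84.3 (adjusted p = 0.93). Of 7 neurogenic genes tested in OPCs 2 fell (4 adjusted over the list alone; adjusted p = 0.15 with an estimated correlation). In committed precursors the chaperone Clu fell by 1.98 ± 0.22 (adjusted p = 0.0054, and 0.16 without the reporter control replicate 2). Of 23 myelin genes 4 rose there when adjusted over the list alone (adjusted p = 0.32 with an estimated correlation). edgeR called 22 genes in OPCs and 45 in committed precursors. The 67 became 35 without the CD1 control, 25 without CD1 CupRap replicate 2, 137 without the reporter control replicate 2 and 155 without reporter CupRap replicate 1. In endothelial cells 29 genes were called, among them the immediate early gene Nr4a1, which fell by 1.80 ± 0.29, and 1 of 17 blood-brain barrier genes, a rise (1 adjusted over the list alone; adjusted p = 0.17 with an estimated correlation). Among the 18 rises were the microglial genes Lyz2 (5.45 ± 0.45), Tyrobp (3.33 ± 0.35) and Trem2 (3.01 ± 0.38), Apoe (1.54 ± 0.20) and the oligodendrocyte gene Mobp (1.97 ± 0.36, not called without reporter CupRap replicate 1, adjusted p = 0.54, or by DESeq2, 0.11). Microglial RNA was estimated at 1.85% ± 0.891 of endothelial sums after CupRap and 0.392% ± 0.332 in controls (SD), and with free RNA subtracted 14 genes were called, 5 higher and 9 lower. In mural cells, the pericytes and muscle cells of vessels, 26 were called, 22 of them higher, among them Rasd1 (2.50 ± 0.29) and the microglial genes Lyz2 (5.32 ± 0.41), Tyrobp (4.202 ± 0.31) and C1qb (2.71 ± 0.27). With doublet calls kept these 3 microglial genes were not called (adjusted p = 0.21, 0.22 and 0.62). Microglial RNA was estimated at 1.71% ± 1.34 of mural sums after CupRap and 0.346% ± 0.182 in controls, and with free RNA subtracted 13 genes were called, 9 higher and 4 lower. Of 20 dissociation genes 3 fell in endothelial cells (5 adjusted over the list alone; adjusted p = 0.20 with an estimated correlation) and of 21 in mural cells 2 rose (3 adjusted over the list alone; adjusted p = 0.14 with an estimated correlation).

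**Figure D4:**
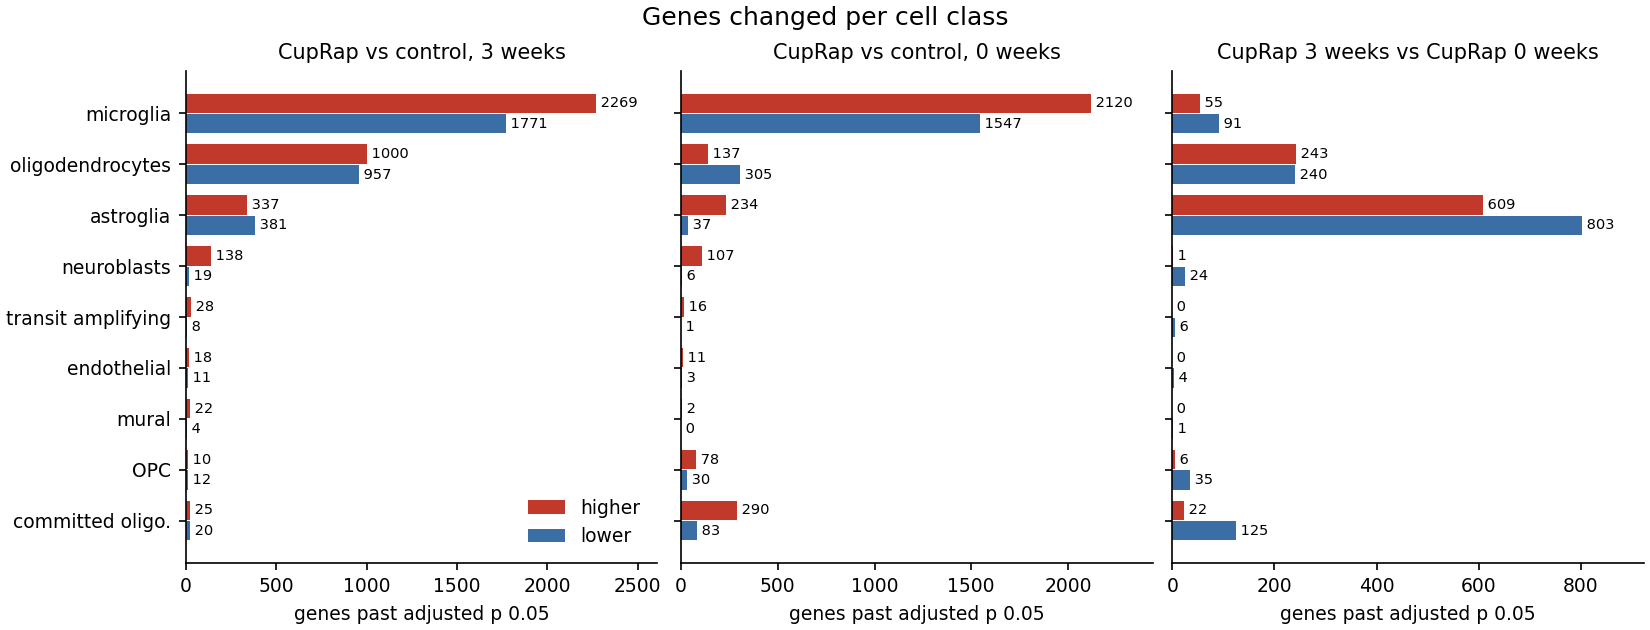
Number of genes called higher and lower (bars) per class and comparison, edgeR's quasi-likelihood test at an adjusted p threshold of 0.05. Microglia lead at 3 and 0 weeks with 4040 and 3667 genes, and astroglia lead between CupRap at 0 and 3 weeks with 1412.

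The EYFP reporter, read in 2 CupRap and 2 control libraries, marked more oligodendrocytes after CupRap. At least 1 EYFP UMI was found in 17.2% and 14.98% of CupRap oligodendrocytes (16.1% ± 1.61, SD) and in 2.30% and 2.41% of control oligodendrocytes (2.35% ± 0.0795). Microglia, which should lack it, showed a UMI in 2.68% and 2.21% of CupRap cells and 1.48% and 1.79% of control cells. The median depth was 11978 and 6811.5 UMIs in CupRap oligodendrocytes, 8131 and 8527 in control ones, 10136 and 4856 in CupRap microglia and 4708 and 4432 in control microglia. After thinning to 3000 UMIs the share was 8.34% ± 0.680 against 0.708% ± 0.109 in oligodendrocytes and 1.15% ± 0.473 in CupRap microglia. Summed per class, EYFP was 9.44-fold higher in CupRap oligodendrocytes (log2 3.24 ± 0.22, SE; edgeR). Its p adjusted over genes was 6.7e-06, and 1.5e-36 to 1.2e-04 over the alternatives. Adjusted over the 10 classes tested, as for the other classes, it was 5.9e-08. EYFP RNA rose 2.06-fold in astroglia (adjusted p = 0.0036, and 0.029 over genes). It was 1.77-fold higher in mural cells (adjusted p = 0.0041) and 1.39-fold in ependymal cells (adjusted p = 0.030), and both calls were lost over genes (0.10 and 0.55). Thinned mural cells carried it in 10.02% of control and 10.21% of CupRap cells. It was at a log2 fold of 0.14 in transit-amplifying cells (adjusted p = 0.56) and 0.22 in neuroblasts (adjusted p = 0.42). In OPCs and committed precursors it was at log2 folds of 1.36 ± 0.35 and 2.69 ± 1.60, with 2 CupRap libraries and 1 control, where the SE comes from the CupRap libraries alone and is no test of a rise. Neuroblasts carried it in 57.8% and 71.1% of control cells and 63.5% and 60.3% of CupRap cells. OPCs carried it in 18 of 69 and 15 of 60 CupRap cells against 8 of 80 in the control replicate 2, and committed precursors in 24.1% and 45.3% against 7.69%. Among CupRap oligodendrocytes, those with EYFP were compared with others of the same depth (114 and 121 cells, 2 libraries). The cyclin gene Ccnd1 was higher in them by a log2 fold of 3.23 ± 0.40 (SE; adjusted p = 1.0e-06), as were the precursor genes Ptprz1 (2.59 ± 0.34) and Pdgfra (5.19 ± 0.76), while Apod, Anln and Hapln2 were lower (−0.66 ± 0.07, −0.88 ± 0.10 and −0.88 ± 0.12, SE). In all 61 of 9400 genes were called, 19 higher and 42 lower.

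**Figure D5:**
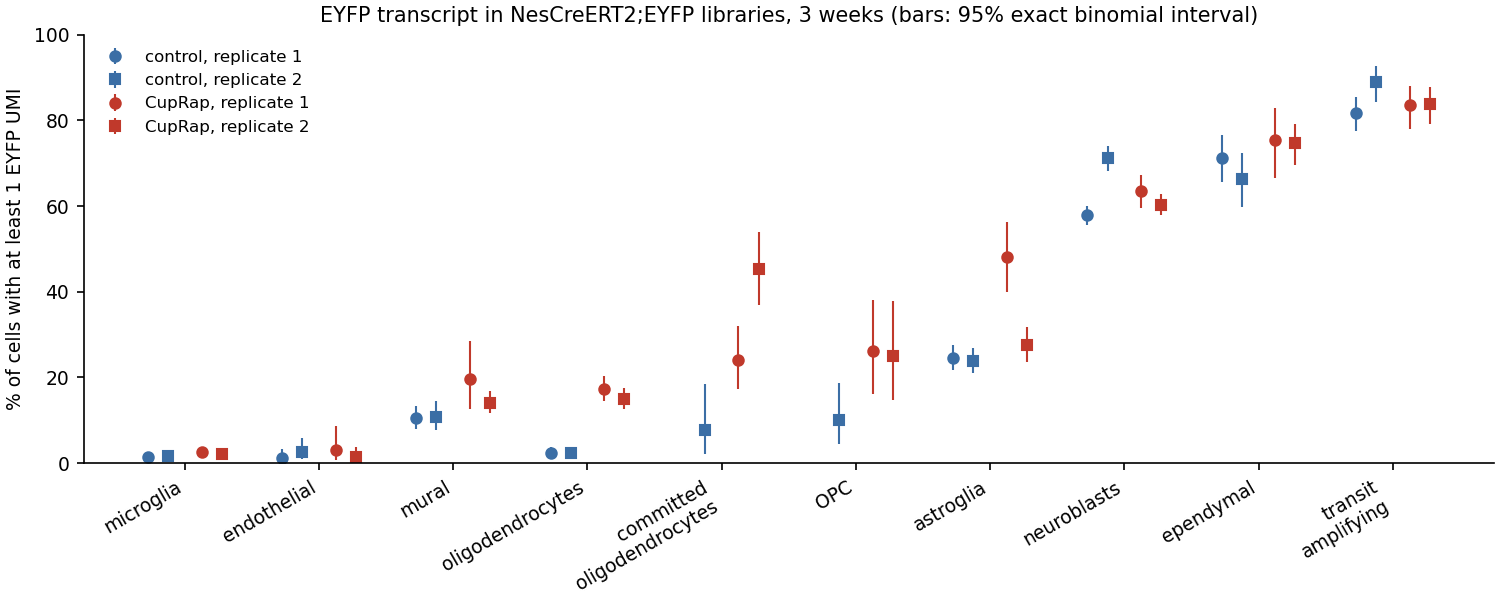
Percent of cells with at least 1 EYFP UMI per class in the 4 libraries of the reporter strain, with exact 95% intervals. CupRap oligodendrocytes lie at 17.2% and 14.98%, control ones at 2.30% and 2.41%.

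At 0 weeks, CupRap against control rested on 2 libraries and 1. The share of neuroblasts fell by 3.48 ± 0.83 on the log2 scale (SE; adjusted p = 0.0016), from 42.3% to 3.78% ± 2.00 (SD, n = 2). Ependymal cells, which line the ventricle, were 5.96% ± 5.32 of CupRap cells and 0.0698% of control cells, a rise by 6.36 ± 1.41 (adjusted p = 0.0014) against 3 control cells. Transit-amplifying cells fell by 2.35 ± 0.81 (adjusted p = 0.034), from 9.21% to 1.81% ± 0.309. Microglia were 52.8% ± 25.5 against 15.4% (adjusted p = 0.12) and oligodendrocytes 13.2% ± 10.5 against 2.07% (adjusted p = 0.054). Without CD1 CupRap replicate 2 at 0 weeks, microglia and astroglia (−3.19) were called. Without replicate 1 oligodendrocytes were called and transit-amplifying cells were not. The latter were also lost without either CD1 CupRap library at 3 weeks (0.074) or either reporter control (0.057), which enter the spread.

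Microglia at 0 weeks already held much of the RNA seen at 3 weeks. Cell cycle genes rose too, with no gene called between the effects at 0 and 3 weeks. Apoe rose from 3018 to 72671 ± 14527 CPM (SD, n = 2), a log2 fold of 4.59 ± 0.31 (SE; adjusted p = 5.6e-05), Igf1 from 2.34 to 139 ± 54.8 CPM (5.89 ± 0.61, adjusted p = 5.4e-04) and Lpl from 44.2 to 1302 ± 65.8 CPM. Fabp5 rose by 5.22 ± 0.27, Lgals3 by 6.74 ± 0.52, Plin2 by 3.43 ± 0.26 and Cst7 by 7.68 ± 0.56. Gpnmb had 1 control UMI and a pooled ratio of 565 (95% interval 101 to 22311), and Colec12 had none and was at least 140-fold higher. The mitosis gene Cenpe rose by 4.11 ± 0.73, Tyms by 2.56 ± 0.43, Mcm6 by 1.37 ± 0.25 and Psat1, for serine synthesis, by 4.69 ± 0.39. Tmem119 fell by 2.91 ± 0.23, P2ry12 by 2.59 ± 0.27, Slc2a5 by 2.32 ± 0.21 and the protease inhibitor Cst3 by 1.85 ± 0.18, from 49722 to 13760 ± 668 CPM. The mTOR inhibitor gene Ddit4 fell by 3.79 ± 0.30, Il7r by 4.51 ± 0.63 and Serpinf1 by 3.97 ± 0.37. Spp1 was at 5391 ± 294 against 240 CPM (4.49 ± 1.497, adjusted p = 0.083, and 5.6e-04 without either reporter control), and Osm at 47.9 ± 17.01 against 28.5 (adjusted p = 0.55). Of 29 disease-associated genes 24 rose (27 adjusted over the list alone; adjusted p = 0.10 with an estimated correlation), and of 24 resting genes 16 fell (16 adjusted over the list alone; adjusted p = 0.17 with an estimated correlation). Of 28 cell cycle genes 17 rose (23 adjusted over the list alone; adjusted p = 0.41 with an estimated correlation). Of 25 interferon genes 21 rose (23 adjusted over the list alone; adjusted p = 0.26 with an estimated correlation), such as Bst2 by 2.09 ± 0.30, of 21 lipid genes 15 rose and 2 fell (16 and 2 adjusted over the list alone; adjusted p = 0.086 with an estimated correlation), and of 28 lysosomal genes 19 rose and 2 fell (19 and 2 adjusted over the list alone; adjusted p = 0.13 with an estimated correlation). Of 17 antigen presentation genes 8 rose (9 adjusted over the list alone; adjusted p = 0.52 with an estimated correlation), such as Cd74 by 2.36 ± 0.41, and of 34 ligands 12 rose and 2 fell (12 and 2 adjusted over the list alone; adjusted p = 0.30 with an estimated correlation). edgeR called 3667 of 13189 genes, 2120 higher and 1547 lower. Of the genes called higher 1545 were also called higher at 3 weeks (391 for independent lists) and of those called lower 1037 (222 for independent lists). CupRap microglia at 0 weeks lay in clusters 24, 35, 38, 42 and 43, control ones in clusters 8 and 21.

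In oligodendrocytes at 0 weeks more genes fell than rose, 305 against 137. The actin-binding gene Anln fell by 4.08 ± 0.40 (SE; adjusted p = 0.0013), from 899 to 53.5 ± 21.5 CPM (SD, n = 2). Serpinb1a fell by 4.87 ± 0.44, Spock3 by 4.34 ± 0.45, the node protein gene Hapln2 by 2.25 ± 0.37, and the protease Klk6 by 2.15 ± 0.30. Tagln2 had 3 control UMIs and a pooled ratio of 66.3 (95% interval 22.6 to 322). H2-K1 rose by 2.26 ± 0.38, and the stress factor Cebpb, with no control UMI, was at least 9.03-fold higher. Of 24 myelin genes 2 fell (2 adjusted over the list alone; adjusted p = 0.77 with an estimated correlation). Of 20 stress response genes 3 rose and 1 fell (7 and 1 adjusted over the list alone; adjusted p = 0.25 with an estimated correlation), and of 20 disease-associated genes 5 rose and 3 fell (12 and 4 adjusted over the list alone; adjusted p = 0.31 with an estimated correlation). Of 15 antigen presentation genes 2 rose (4 adjusted over the list alone; adjusted p = 0.089 with an estimated correlation). The sums held an estimated 2.75% ± 1.63 microglial RNA after CupRap and 0.0912% in the control, and with free RNA subtracted the test of antigen presentation at the preset correlation had an adjusted p of 0.0010. The 2 CupRap libraries differed. Mog was at 0.49 ± 0.67 (adjusted p = 0.73), at −0.87 without replicate 1 (0.034) and at 1.17 without replicate 2 (0.016). edgeR called 442 genes, 137 higher and 305 lower, 402 with free RNA subtracted, 1641 without CD1 CupRap replicate 1, 698 without replicate 2, and 267 and 269 without reporter control replicates 1 and 2. Of the called genes 102 higher and 237 lower ones were called likewise at 3 weeks (11.9 and 25.6 for independent lists). CupRap cells lay mostly in clusters 20 and 44, the latter led by replicate 2, and control cells in clusters 6 and 19.

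In astroglia at 0 weeks 15 of 26 reactive genes rose (24 adjusted over the list alone; adjusted p = 0.089 with an estimated correlation) and 11 of 23 cholesterol synthesis genes fell (1 higher and 20 lower adjusted over the list alone; adjusted p = 0.12 with an estimated correlation). Gfap rose from 32.4 to 1543 ± 740 CPM (SD, n = 2), by 5.58 ± 0.50 (SE; adjusted p = 1.1e-04). Serpina3n rose by 4.08 ± 0.49, the adhesion receptor Cd44 by 3.26 ± 0.42, C4b by 2.42 ± 0.31, S100a6 by 2.25 ± 0.29 and the stress factor Nupr1 by 4.199 ± 0.46. The sterol genes Idi1 and Cyp51 fell by 2.34 ± 0.36 and 1.98 ± 0.25. Egfr was at 255 ± 33.1 against 385 CPM (adjusted p = 0.26). Of 21 stress response genes 4 rose and 1 fell (11 and 2 adjusted over the list alone; adjusted p = 0.12 with an estimated correlation). Antigen presentation genes rose in 4 of 15 cases (11 adjusted over the list alone; adjusted p = 0.17 with an estimated correlation) and interferon genes in 2 of 19 (9 adjusted over the list alone; adjusted p = 0.20 with an estimated correlation). Of 17 neurogenic genes 2 fell (3 adjusted over the list alone). edgeR called 271 genes, 234 higher and 37 lower, 879 without CD1 CupRap replicate 1 and 46 without replicate 2. Microglial RNA was estimated at 3.40% ± 1.69 of these sums after CupRap and 0.165% in the control, and with free RNA subtracted 123 genes were called. Of the genes called higher 110 were called higher at 3 weeks (5.52 for independent lists). Control cells lay mostly in clusters 15, 18 and 29 and CupRap cells in clusters 15, 22 and 29, those of replicate 2 most in cluster 22.

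In committed precursors at 0 weeks 10 of 24 myelin genes rose (15 higher and 1 lower adjusted over the list alone; adjusted p = 0.18 with an estimated correlation). The control held 30 cells of cluster 17 and 16 of cluster 41, and the CupRap replicates 64 and 69 and 204 and 216, so a shift between these clusters was not separated from a change within them. Mobp rose from 31.4 to 1140 ± 360 CPM (SD, n = 2), by 5.18 ± 0.52 (SE; adjusted p = 2.9e-04), Mag by 2.25 ± 0.28, Tspan2 by 2.13 ± 0.27 and the calcium channel gene Itpr2 by 2.17 ± 0.37. In OPCs C4b rose by 6.83 ± 0.49, from 5.45 to 636 ± 160 CPM (adjusted p = 3.8e-14), and the angiogenic factor Vegfa fell by 1.80 ± 0.32. Cldn11 had 1 control UMI and a pooled ratio of 93.5 (95% interval 16.7 to 3707). Of 28 cell cycle genes 6 rose in OPCs when adjusted over the list alone (adjusted p = 0.28 with an estimated correlation), and of 18 myelin genes 2 rose (5 adjusted over the list alone; adjusted p = 0.16 with an estimated correlation). edgeR called 373 and 108 genes in the 2 classes, 481 in all and 303 without CD1 CupRap replicate 2. In neuroblasts it called 113 genes, 251 without CD1 CupRap replicate 1. With free RNA subtracted it called 0 of 13425, with 577 at an unadjusted p under the threshold, and the subtraction was not run with DESeq2. Microglial RNA was estimated at 5.51% ± 3.88 of neuroblast sums after CupRap and 0.0853% in the control. Of 23 cholesterol genes 4 fell in neuroblasts before it (11 adjusted over the list alone; adjusted p = 0.091 with an estimated correlation).

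Between 0 and 3 weeks after CupRap in CD1 (2 libraries each), 15 of 26 reactive genes fell in astroglia (22 adjusted over the list alone; adjusted p = 0.22 with an estimated correlation) and 8 of 15 activation genes rose (8 adjusted over the list alone; adjusted p = 0.30 with an estimated correlation). Gfap fell by 3.86 ± 0.34 (SE; adjusted p = 1.1e-04), from 1543 ± 740 to 107 ± 8.09 CPM (SD). Serpina3n fell by 3.62 ± 0.48, Nupr1 by 3.70 ± 0.43, the annexin gene Anxa2 by 3.52 ± 0.50, S100a6 by 2.43 ± 0.23 and C4b by 2.19 ± 0.25. The neurogenic factors Dlx1, Dlx2 and Helt rose by 2.64 ± 0.28 (adjusted p = 1.2e-04), 2.72 ± 0.37 and 2.70 ± 0.32, the neuronal tubulin gene Tubb3 by 2.44 ± 0.25 and Rrm2, for DNA synthesis, by 1.81 ± 0.25. Dlx1 and Tubb3 are also leading genes of neuroblast clusters. Neuroblasts were 3.78% ± 2.00 of CD1 CupRap cells at 0 weeks and 34.0% ± 1.83 at 3 weeks, and their free RNA was not estimated or subtracted, so these rises were not shown to come from astroglia. Dormancy genes fell in 10 of 18 cases (13 adjusted over the list alone; adjusted p = 0.46 with an estimated correlation) and stress response genes in 5 of 21 (12 adjusted over the list alone; adjusted p = 0.27 with an estimated correlation). Neurogenic genes rose in 6 of 17 cases (8 adjusted over the list alone; adjusted p = 0.25 with an estimated correlation), cell cycle genes in 10 of 27 (11 adjusted over the list alone; adjusted p = 0.27 with an estimated correlation) and cholesterol genes in 5 of 23 (5 adjusted over the list alone; adjusted p = 0.57 with an estimated correlation). Of 22 ligand receptors 1 rose and 9 fell (2 and 13 adjusted over the list alone; adjusted p = 0.20 with an estimated correlation). At 0 weeks astroglia lay most in cluster 15 in replicate 1 (30 cells) and cluster 22 in replicate 2 (142), and at 3 weeks in cluster 29 (71 and 50). edgeR called 1412 genes, 609 higher and 803 lower, 500 without CD1 CupRap replicate 2 at 0 weeks, and 263 and 331 without replicates 1 and 2 at 3 weeks.

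In oligodendrocytes over the same interval 243 genes rose and 240 fell, among the latter 7 of 20 stress response genes (2 higher and 11 lower adjusted over the list alone; adjusted p = 0.20 with an estimated correlation). Serpinb1a rose by 4.08 ± 0.40 (SE; adjusted p = 0.0035), from 15.7 ± 1.13 to 265 ± 22.7 CPM (SD), Anln by 2.87 ± 0.35, Spock3 by 3.02 ± 0.40, Klk6 by 1.93 ± 0.25, Sez6l2 by 2.89 ± 0.47 and Folh1 by 2.74 ± 0.32. Nupr1 fell by 3.92 ± 0.41 (adjusted p = 0.0035), the growth arrest genes Gadd45b and Cdkn1a by 4.14 ± 0.51 and 5.23 ± 0.77, the metallothionein Mt2 by 3.23 ± 0.60 and Atf4 by 1.31 ± 0.23. The stress hormone gene Gdf15 held 1 UMI at 3 weeks, a pooled ratio of 0.00785 (95% interval 0.000198 to 0.0443). Spp1, which is abundant in microglia, fell by 3.82 ± 0.41. These sums held an estimated 2.75% ± 1.63 microglial RNA at 0 weeks and 0.458% ± 0.0207 at 3 weeks (SD). Subtracting free RNA left 296 called genes, 174 higher and 122 lower, and Spp1 was no longer tested (with doublets kept its adjusted p was 0.20), while Nupr1, Gadd45b, Cdkn1a, Mt2 and Atf4 were still called (adjusted p of 0.0062 to 0.035). Of 21 dissociation genes 7 fell (1 higher and 12 lower adjusted over the list alone; adjusted p = 0.20 with an estimated correlation). Of 20 disease-associated genes 2 rose and 4 fell (3 and 8 adjusted over the list alone; adjusted p = 0.51 with an estimated correlation). Of 24 myelin genes 2 rose (4 adjusted over the list alone; adjusted p = 0.60 with an estimated correlation), and of 23 cholesterol genes 2 rose (3 adjusted over the list alone; adjusted p = 0.57 with an estimated correlation). At 0 weeks the cells lay mostly in clusters 20 (102 and 186 cells) and 44 (124 and 574), and at 3 weeks in cluster 19 (313 and 105), with 9 and 3 in cluster 44, so a shift between clusters was not separated from change within them. edgeR called 6 without CD1 CupRap replicate 1 at 3 weeks and 135 without replicate 2, 2912 and 309 without replicates 1 and 2 at 0 weeks, and 240, 237, 315 and 310 without the reporter control and CupRap replicates. Without replicate 1 at 3 weeks the named genes other than Serpinb1a and Nupr1 had an adjusted p of 0.058 to 0.22. Without replicate 2 at 3 weeks the calls of Sez6l2, Cdkn1a, Gadd45b, Mt2 and Atf4 were lost (0.053 to 0.13), and without replicate 2 at 0 weeks those of Serpinb1a and Spock3 (0.073 and 0.083).

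In microglia over this interval 10 of 28 cell cycle genes fell (25 adjusted over the list alone; adjusted p = 0.20 with an estimated correlation). Tpx2, of the mitotic spindle, fell by 3.65 ± 0.47 (SE; adjusted p = 0.014), Stmn1 by 1.46 ± 0.15, Psat1 by 2.17 ± 0.24, Phgdh by 1.25 ± 0.18 and the growth factor gene Gas6 by 1.81 ± 0.18. Lyz2 rose from 1696 ± 198 to 8139 ± 2036 CPM (SD; 2.26 ± 0.24, adjusted p = 0.0093), Ms4a7 by 3.03 ± 0.32, Atp6v0d2 by 2.42 ± 0.22 and Gpnmb by 1.44 ± 0.16. Of 29 disease-associated genes 5 rose (7 higher and 4 lower adjusted over the list alone), of 24 resting genes 1 rose (2 adjusted over the list alone), of 21 lipid genes 2 rose (2 higher and 2 lower adjusted over the list alone), of 28 lysosomal genes 1 rose and 1 fell (3 and 5 adjusted over the list alone) and of 17 antigen presentation genes 1 rose (3 adjusted over the list alone; adjusted p = 0.50 with an estimated correlation). Cluster 51 held 133 and 38 cells at 0 weeks and 1 and 3 at 3 weeks. edgeR called 146 genes, 55 higher and 91 lower. It called 78 without reporter control replicate 1 or 2, 89 without reporter CupRap replicate 1 or 2, and 6 without CD1 CupRap replicate 2 at 3 weeks. Without replicate 1 at 3 weeks it called 0 of 13123, with 1183 at an unadjusted p under the threshold, and the named genes had an adjusted p of 0.0915 to 0.22. Without replicate 2 the calls of Lyz2 and Gas6 held and those of the others were lost (0.054 to 0.16). DESeq2 called 207 with all libraries.

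The change between the CD1 controls at 0 and 3 weeks was set against these recoveries as a difference of differences, with 1 control library at each time. In astroglia, oligodendrocytes and microglia edgeR then called 0 genes each, with 1156, 1004 and 1006 at an unadjusted p under the threshold, and DESeq2 was not run on this difference. The adjusted p of the named genes was 0.068 for S100a6 and 0.14 to 1 for the others. Cdkn1a in oligodendrocytes was at 0.02 (adjusted p = 1). The recovery values thus stand for 2 libraries against 2 without a control for time or batch. The 0-week CupRap libraries enter this comparison and that with the 0-week control, so a chance value in them moves both in opposite ways.

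The response at 3 weeks was compared between the strains, which differ also in the reporter, the gene list and perhaps the batch. Across genes, which are not independent replicates, the log2 fold changes of the strains had a Spearman correlation of 0.711 in microglia, 0.584 in oligodendrocytes and 0.353 in astroglia. It was 0.197 in transit-amplifying cells, 0.231 in neuroblasts, 0.130 in endothelial cells, 0.227 in mural cells, 0.0935 in OPCs and 0.238 in committed precursors. Of 1584 microglial genes called in both strains 1582 had the same direction, as had 272 of 273 in oligodendrocytes and 90 of 91 in astroglia. In the other classes these were 9 of 10 (transit-amplifying cells), 27 of 27 (neuroblasts), 3 of 3 (endothelial cells), 7 of 8 (mural cells), 3 of 6 (OPCs) and 1 of 1 (committed precursors). The difference itself was called for 1 gene in astroglia and 1 in transit-amplifying cells among the 7 classes tested in every library. Gsn, an actin-severing gene also found in mature oligodendrocytes, rose from 43.0 to 234 CPM in astroglia of the reporter strain and was at 33.0 and 34.0 CPM in CD1 (difference 2.40 ± 0.32, SE; adjusted p = 0.016). CupRap astroglia lay most in cluster 29 in CD1 (71 and 50 cells, with 6 and 5 in cluster 22) and in cluster 22 in the reporter strain (53 and 244), so another mix of cells was not separated from a strain difference. Hist1h3b, 1 of many near-identical histone genes, differed by −1.88 ± 0.25 in transit-amplifying cells (adjusted p = 0.026). In microglia edgeR called 0 genes, with 779 at an unadjusted p under the threshold and 21 called by DESeq2. In oligodendrocytes it called 0, with 273 at an unadjusted p under the threshold and 1 called by DESeq2, and in neuroblasts 0, with 238 and 1. The count of 2 was 0 without CD1 CupRap replicate 1 at 3 weeks or reporter control replicate 2, 5 without CD1 CupRap replicate 2 at 3 weeks, 1 and 4 without reporter CupRap replicates 1 and 2, and 30 and 35 without CD1 CupRap replicates 1 and 2 at 0 weeks. The list tests called 31 of 116 differences, 22 higher in the reporter strain and 9 lower, and 0 of them with an estimated correlation. With it 10 of the 62 list tests called at 3 weeks were kept, 0 of the 70 at 0 weeks and 0 of the 62 between the times.

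In the coordinates of mm10, Gpnmb (ENSMUSG00000029816) lies on chromosome 6 at 49036546 to 49070929, Igf1 (ENSMUSG00000020053) on chromosome 10 at 87858265 to 87937042, Apoe (ENSMUSG00000002985) on chromosome 7 at 19696109 to 19699188 and P2ry12 (ENSMUSG00000036353) on chromosome 3 at 59216272 to 59262871. Tspan2 (ENSMUSG00000027858) lies on chromosome 3 at 102734529 to 102801513, Gfap (ENSMUSG00000020932) on chromosome 11 at 102887336 to 102900912, Msmo1 (ENSMUSG00000031604) on chromosome 8 at 64718139 to 64733792 and Spp1 (ENSMUSG00000029304) on chromosome 5 at 104435118 to 104441050. All are protein-coding genes, and reads were taken from their 3' ends.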

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

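All tests of this part were chosen after the results were seen, except those of the differences between the strains and of the recovery against the controls.

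The first pattern weighed is the change of 4040 genes in microglia at 3 weeks. A few abundant genes cannot make it: the 100 most abundant held 50.8% ± 2.81 (SD) of microglial UMIs after CupRap and 34.1% ± 0.957 in controls, Apoe alone 11.7% ± 1.18 and 0.196% ± 0.103, yet without them 99.3% of the other called genes were still called (3922 of 3948). Unequal depth is argued against by 2696 genes called with every library thinned to the shallowest, 2556 of them among the 4040. Border macrophages counted as microglia are argued against as well, since their own markers allow a share of 0.749%, which gives 1.37% of the median rise (quartiles 0.798 to 2.16), and Ms4a7 would need 13.4%. A response of microglia to demyelination may remain as a hypothesis, with cuprizone, rapamycin and the loss of myelin not separable in this design.

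The second pattern is the set of 138 genes that rose in neuroblasts at 3 weeks while cholesterol genes fell. Free microglial RNA, estimated from a fixed list of 10 genes that are also microglia markers, predicts 91.7% of the median rise (quartiles 71.7 to 103), and 50% of it or more for 113 of 132 genes outside the lists. For genes matched on expression it predicts a rise of 0.624% (1.16% at most in 1000 draws), against 443%. With it subtracted the median log2 rise went from 2.53 to 1.19 and 9 of 138 genes were still called, so free microglial RNA may give most of these rises. It made up 1.37% of CupRap sums, too little for its subtraction to change the falls. The 10 cholesterol genes kept 99.6% of their median fall (−0.94 before and −0.93 after, SD 0.26), and 6 were still called. Free astroglial RNA, not estimated, and an untested lower sterol synthesis of neuroblasts stay open.

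The third pattern is the EYFP share of 16.1% in CupRap oligodendrocytes against 2.35% in controls. Unequal depth is argued against by 8.34% ± 0.680 against 0.708% ± 0.109 in thinned cells. Free EYFP RNA is argued against by microglia, which held 11.1% of the EYFP level of oligodendrocytes in the same libraries, and doublets by markers of 5 other neural classes, which allow 0.811% of the EYFP (0.840 and 0.781 in the 2 libraries). Descent of some oligodendrocytes from labelled precursors may be put forward as a hypothesis, and a reporter switched on in the oligodendrocyte lineage itself stays open, as the labels do not give the time of induction.

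Splits of the 7 libraries at 3 weeks into 4 and 3 were counted, 34 in all with the real one. Over these 34, which move libraries across strains, the real count was the highest for microglia (4040 genes, highest other 1), oligodendrocytes (1957, highest other 528), astroglia (718, highest other 334), neuroblasts (157, highest other 16) and mural cells (26, highest other 19). It was not for transit-amplifying cells (2 splits as large, 36 genes, highest other 40), endothelial cells (3 splits, 29 genes, highest other 43) and the gene lists called over 7 classes (7 splits, 53 lists, highest other 66). The splits that keep the strains balanced are 18, too few for a share under 0.05, so chance is not excluded for any class. Among them the highest other count was 1 in microglia, 528 in oligodendrocytes, 334 in astroglia, 4 in neuroblasts, 19 in mural cells, 17 in transit-amplifying cells, 19 in endothelial cells and 56 for the lists.

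Other results stood out because a test of the difference between 2 groups' effects called them. Between the strains at 3 weeks these were Gsn in astroglia (2.40 ± 0.32, SE; adjusted p = 0.016, and 0.42, 0.12 and 0.24 without CD1 CupRap replicate 1, replicate 2 and reporter control replicate 2). CupRap astroglia lay in other clusters by strain, so cell mix and batch are not separated from strain. Hist1h3b in transit-amplifying cells was at −1.88 ± 0.25 (adjusted p = 0.026, and 0.093 to 0.25 without any 1 of 6 libraries, the CD1 CupRap, reporter control and reporter CupRap replicates). In committed precursors Tspan9 had 0 UMIs in the CD1 control and 74.1 CPM in CD1 CupRap (adjusted p = 0.014, and 0.072, 0.070 and 0.087 without reporter CupRap replicate 1 and CD1 CupRap replicates 1 and 2 at 0 weeks). Tmem2 was at −3.89 ± 0.59 there (adjusted p = 0.035, and 0.072, 0.125 and 0.15 without the same libraries). The committed precursors of the CD1 control were 27 cells of cluster 17 and 1 of cluster 41, where each other library tested at 3 weeks held 21 to 81 of the latter, so the same holds there. Lists whose effect differed between strains numbered 31 of 116 by camera, 0 of them with an estimated correlation. Between the effects at 3 and 0 weeks in CD1 these were Junb in endothelial cells (−2.98 ± 0.59, adjusted p = 0.013), and Tubb3 (−5.29 ± 0.93) and C4b (−5.39 ± 0.95) in OPCs (adjusted p = 0.0089 each). Junb was at 92.1 CPM in the control and 287 after CupRap at 0 weeks, and at 317 and 127 at 3 weeks. Tubb3 was at 3.27 and 30.5 and then 87.8 and 18.2. C4b was at 5.45 and 636 and then 27.9 and 76.3. Junb was lost without CD1 CupRap replicate 2 at 3 weeks (adjusted p = 0.12) or reporter CupRap replicate 1 or 2 (0.094 and 0.11). Tubb3 and C4b were lost without CD1 CupRap replicate 1 at 3 weeks (0.17 and 0.073), and the CD1 controls, 1 at each time, could not be left out.

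A pair of unnamed clusters stood out because they lie outside the classes compared and above their control level. Cluster 48, led by Eomes, Neurog2, Slc17a6 and Neurod1, held 0.527% ± 0.288 of CupRap cells at 3 weeks and 0.0849% ± 0.0299 of control cells. Cluster 54, with a median of 615.5 UMIs per cell and oligodendrocyte genes, held 0.519% ± 0.602 and no control cells, with 33 cells in CD1 CupRap replicate 1, 50 in reporter CupRap replicate 1 and 1 in replicate 2.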

How the results depend on the processing

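Counts of called genes moved with several settings and are given with the main value in brackets. The settings of a common UMI minimum, free RNA subtracted, the crossed block, thinned EYFP cells and the blocked and subtracted list tests were chosen after the results were seen. The cause of each move was not tested. CD1 alone (2 libraries against 1) gave 3504 over the classes (6963), 2566 in microglia (4040), 410 in oligodendrocytes (1957), 368 in astroglia (718), 54 in neuroblasts (157) and 390 in OPCs with committed precursors (67) at 3 weeks. The reporter strain alone gave 2397 in microglia (4040) and 101 in neuroblasts (157) at 3 weeks. All 10 libraries in the 3-week model gave 4555 over the classes (6963), 480 in oligodendrocytes (1957), 243 in astroglia (718), 101 in neuroblasts (157) and 226 in OPCs with committed precursors (67) at 3 weeks. With the conflicting CD1 control added the count was 221 in OPCs with committed precursors (67) at 3 weeks. Both CD1 controls as 1 group gave 7187 over the classes (4526), 1437 in oligodendrocytes (442), 702 in astroglia (271), 235 in neuroblasts (113) and 963 in OPCs with committed precursors (481) at 0 weeks.

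DESeq2 called 158 in OPCs with committed precursors (67) at 3 weeks. It gave 186 in neuroblasts (113) and 270 in OPCs with committed precursors (481) at 0 weeks. It gave 107 in neuroblasts (25) and 51 in OPCs with committed precursors (188) between 0 and 3 weeks. Without the filter on low counts edgeR called 1423 in astroglia (718), 604 in neuroblasts (157) and 617 in OPCs with committed precursors (67) at 3 weeks. It gave 7027 over the classes (4526), 1330 in oligodendrocytes (442), 766 in astroglia (271), 311 in neuroblasts (113) and 868 in OPCs with committed precursors (481) at 0 weeks. It gave 5270 over the classes (2077), 975 in microglia (146), 1646 in oligodendrocytes (483), 2145 in astroglia (1412), 220 in neuroblasts (25) and 616 in OPCs with committed precursors (188) between 0 and 3 weeks. With doublet calls kept there were 300 in neuroblasts (157) and 163 in OPCs with committed precursors (67) at 3 weeks. It gave 362 in neuroblasts (113) at 0 weeks. It gave 342 in neuroblasts (25) between 0 and 3 weeks. With free RNA subtracted edgeR called 18 in neuroblasts (157) at 3 weeks. It gave 123 in astroglia (271) and 0 in neuroblasts (113) at 0 weeks. It gave 296 in oligodendrocytes (483) and 0 in neuroblasts (25) between 0 and 3 weeks. A common UMI minimum gave 298 in oligodendrocytes (483) between 0 and 3 weeks. The 2 differences between strains became 31 with DESeq2, 5 with doublet calls kept, 264 without the filter and 43 with the replicate block.

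The replicate number as a block gave 281 in OPCs with committed precursors (67) at 3 weeks. It gave 119 in oligodendrocytes (442) and 116 in astroglia (271) at 0 weeks. It gave 130 in neuroblasts (25) and 468 in OPCs with committed precursors (188) between 0 and 3 weeks. Only 2 pairs can be formed in a strain, and the labels do not say whether libraries of the same replicate number were paired. Across genes, the difference between replicates in reporter controls had a correlation with that in reporter CupRap libraries of 0.078 in microglia, 0.147 in oligodendrocytes, 0.212 in astroglia, 0.122 in transit-amplifying cells, 0.155 in neuroblasts, −0.025 in endothelial cells and −0.0019 in mural cells. Between CD1 CupRap at 0 and 3 weeks these were −0.436, −0.346, 0.0015, −0.214, −0.328, −0.017 and 0.287. With the replicate block 0 classes passed for the shares at 3 weeks (3 without), microglia at 1.67 and astroglia at −1.90 (both adjusted p = 0.068, against 0.0056 and 0.0054). Crossed pairs of the CD1 CupRap libraries gave 1176 genes in oligodendrocytes (483) and 454 in OPCs with committed precursors (188).

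Set against the change between the CD1 controls, the recovery gave 1 gene over the 7 classes (2077), 2 in OPCs with committed precursors (188) and 0 in each of microglia, oligodendrocytes, astroglia and neuroblasts, where edgeR had 1006, 1004, 1156 and 618 at an unadjusted p under the threshold. With an estimated correlation 10 of 225 list tests were kept, all at 3 weeks. TMM over classes left 1 class of 3 in the shares at 3 weeks, with microglia at 1.498 (adjusted p = 0.13), and doublet calls kept gave 5 classes at 0 weeks (3). EYFP was found in 8.64% of CupRap oligodendrocytes with at least 2 UMIs and in 8.34% after thinning (16.1%).

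Leaving out 1 library at a time gave 1294 to 2015 in oligodendrocytes (1957), 352 to 649 in astroglia (718), 92 to 162 in neuroblasts (157) and 25 to 155 in OPCs with committed precursors (67) at 3 weeks. It gave 267 to 1641 in oligodendrocytes (442), 46 to 879 in astroglia (271), 80 to 251 in neuroblasts (113) and 303 to 669 in OPCs with committed precursors (481) at 0 weeks. It gave 281 to 5411 over the classes (2077), 0 to 148 in microglia (146), 6 to 2912 in oligodendrocytes (483), 263 to 1649 in astroglia (1412), 4 to 167 in neuroblasts (25) and 47 to 499 in OPCs with committed precursors (188) between 0 and 3 weeks. The differences between strains ranged from 0 to 35 (2) and the classes called at 0 weeks from 2 to 5 (3).

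In oligodendrocytes, Mog at 0 weeks was at −0.87 without CD1 CupRap replicate 1, 1.17 without replicate 2 and 0.49 with both. Their Cdkn1a between the times was at 0.023 as a difference of differences, against −5.23. Of 507 values of the 31 comparison results, 371 were the same, 3 weaker and 133 moved. Of 4201 values of 231 named genes and further classes, 3775 were the same, 402 weaker, 21 stronger, 1 moved and 2 reversed. Leaving out a library made 201 of 1859 weaker, the block 23 of 231, all 10 libraries 26 of 108, the reporter strain alone 19 of 108, CD1 alone 16 of 99, DESeq2 12 of 218, free RNA subtraction 13 of 211, kept doublets 17 of 230, the common UMI minimum 15 of 222 and the difference of differences 38 of 39. RLE size factors made 3 of 223 weaker and the stricter cell filter 8 of 230. The other clustering resolution was run on cell shares only and left all 7 of its values here the same. No gene, list or reporter result was refitted with it.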

Other observations

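Microglia at 3 weeks also changed RNA of ligands not named so far. The complement gene C3 rose by 4.51 ± 0.34 (log2, SE; 4 CupRap and 3 control libraries, adjusted p = 1.2e-06), the chemokine Cxcl16 by 1.98 ± 0.14, the growth factors Hgf and Vegfb by 2.09 ± 0.32 and 1.09 ± 0.13, and Pdgfa, a mitogen of OPCs, by 0.80 ± 0.16. Csf1 and Il1b rose by 2.43 ± 0.58 and 2.46 ± 0.60 (adjusted p = 0.035 each). Pdgfb fell by 0.82 ± 0.13, Pros1 by 0.45 ± 0.12 and Ccl2 by 1.00 ± 0.26, while Tgfb1 was at −0.12 (adjusted p = 0.54) and Tnf at −0.73 (adjusted p = 0.47). Of the mitochondrially encoded genes mt-Co1 and mt-Co3 rose by 1.85 ± 0.18 and 1.90 ± 0.20. These genes were not refitted with single libraries left out.

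Cluster 48, whose leading genes are those of excitatory neuron precursors, was picked for its higher share after CupRap at 3 weeks, so no test on these libraries was used. Its CupRap libraries at 3 weeks ranged from 0.170% up and its controls to 0.105% at most, on 81 and 12 cells. At 0 weeks the order was the reverse, with 8 of 4298 cells in the CD1 control and 1 cell in the 2 CupRap libraries.

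The 2 CD1 controls held 3 ependymal cells at 0 weeks and 0 at 3 weeks, while the reporter controls held 4.82% of such cells. The rise of ependymal cells at 0 weeks therefore rests on CD1 controls that held almost none, and the area dissected was not given per library. Cluster 52, with leading genes of another class, held 13 CupRap and 50 control cells at 3 weeks.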
